A study of Mus musculus with 8 samples.

How the data were processed

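Total RNA was measured in 8 samples of mouse haematopoietic precursor cells on Affymetrix arrays, 1 sample per array, after conversion to biotin-labelled sense-strand DNA. The cells came from iSOX7, a derivative of the Ainv18 embryonic stem cell line in which doxycycline induces the transcription factor SOX7. Per the labels' protocols, FLK1+ cells from embryoid bodies were kept in liquid blast culture, sorted as CD41+ and CD34−, and then cultured for 12 or 24 h with or without doxycycline. Groups and replicate numbers were taken from the sample titles, which gave 4 groups of 2, with 0 data columns left unmapped. Nothing in the sources used here says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Cells treated with doxycycline but lacking the transgene were not analysed here.

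The values deposited by the authors were log2 expression values, 1 column per array over 16348 probe sets. Per the submitters' processing notes, they were made with RMA in Affymetrix Power Tools, without versions. RMA corrects background, normalizes between arrays and summarises probes on the log2 scale. The log2 scale was read from that note and from the range of the values, and centring beyond RMA and any filter on probe sets were not given in the sources used here. A genome build was likewise not given in the sources used here, so no coordinates are printed. Scanner files and detection calls were not used here, so no background level is known and dim probe sets carry no bound. Array medians ran from 6.40 to 6.61. Sequencing depth has no counterpart on arrays, and the number of arrays limits the precision.

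Probe sets were named through the platform annotation: 14785 had 1 gene symbol, 950 had several and 613 had none. The 14785 named 14683 genes, 14740 of them matched by Entrez identifier, and 0 symbols needed updating. No gene was named from a probe set with several symbols, and a gene with several probe sets was represented by the one with the highest mean over the 8 arrays. Symbols and values identify each gene here.

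Each probe set was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 mean per group over all 8 arrays, which left 4 residual degrees of freedom and a prior of 3.44. Contrasts were doxycycline against none at 12 h and at 24 h, the difference of those effects, and 24 h against 12 h without and with doxycycline. A further model with terms for doxycycline and time compared 4 arrays with 4 and left 5 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 16348 probe sets, and a probe set passed at an adjusted p under 0.05. No filter was applied. Changes are given as log2 differences ± standard error from this fit, with 2 samples per group unless stated, and the adjusted p of a probe set or gene is from limma with Benjamini-Hochberg. The adjusted p of a list or of its shift against other probe sets is from camera, adjusted over the 24 lists of a contrast, unless fry is named. The caveola, retinoic acid and heme lists were adjusted over their 6 tests.

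Before the data were examined, 25 gene lists, the tests, the alternatives and a rule for naming genes were fixed. The rule took Sox7 first, then the 10 largest rises and the 10 largest falls at 12 h and at 24 h among passing probe sets with 1 symbol whose samples did not overlap. It took the 5 largest in each direction for the other contrasts, and up to 4 members of each list with the smallest p. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, which left 24 lists. Camera compares a list with all other probe sets. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run beside it. Klf1, Gata1, Spi1, Etv6, Nfe2, Bmx, Sox17, Sox18 and Myc each stand in more than 1 list.

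The titles number the replicates alike in all groups. Deviations from the group means correlated across probe sets between samples of the same number, with r = 0.371 between the groups with and without doxycycline at 12 h and r = 0.428 at 24 h, and r from 0.298 to 0.428 over all pairs of groups. With 2 samples per group the deviations mirror each other, so both pairs of a time share 1 correlation. For the comparison over both times, which holds 4 pairs, the numbers were therefore treated as pairing the samples, and the fit with the number as a block is given beside it. A comparison at 1 time holds only 2 pairs, so its blocked count is given with the other alternatives.

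The alternatives were a repeated quantile normalization, centring of each array on its median, eBayes with an intensity trend or made robust, leaving out the dimmest 33.3% of probe sets, 1 probe set per gene, array quality weights, the replicate number as a block, a fit of only the groups compared, and leaving out each array in turn. The pipeline was tested on 10 simulated data sets of 16348 probe sets. At 12 h it recovered 63.1% of changes of 1 on the log2 scale and 97.3% of changes of 2, with 5.6% false calls. At 24 h these shares were 61.1%, 97.7% and 6.2%, and over both times 91.1%, 99.4% and 5.1%. The simulated changes were the same at both times, so the test of the difference had nothing to recover. It gave 0 calls, which does not measure its power. A simulated shift of -0.5 in the erythroid list at 24 h was called in 10 of 10 data sets, with 1 call among 230 tests of unchanged lists. The simulated probe sets varied independently of each other. The simulations therefore do not show how often unchanged lists are called when their genes vary together. Figures were drawn with matplotlib 3.10.9.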

Results

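Gene expression was measured in 8 samples of sorted CD41+ haematopoietic precursors, 2 in each of 4 groups: without and with doxycycline at 12 h, and without and with doxycycline at 24 h. Doxycycline switched on SOX7, a SoxF transcription factor of early blood and endothelial precursors, and the series asked which genes respond to it. The arrays correlated with r from 0.9732 to 0.9915 over 16348 probe sets. Within a group r was 0.991 at 12 h without doxycycline, 0.9915 at 12 h with it, 0.9831 at 24 h without it and 0.9914 at 24 h with it. The second array without doxycycline at 24 h stood apart, with an upper quartile of 8.19 and an SD over probe sets of 2.355, against 8.38 to 8.57 and 2.433 to 2.517 on the other 7 arrays.

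Markers of smooth muscle and mesenchyme followed the replicate number, with a list mean of 5.97 to 6.21 on the 4 arrays of replicate 1 and 6.83 to 7.01 on the 4 arrays of replicate 2. The endothelial list mean was lower in replicate 2 than in replicate 1 in each group, at 7.03 against 7.58 and 6.76 against 7.57 without doxycycline at 12 h and 24 h, and 7.87 against 8.21 and 8.02 against 8.31 with it. The megakaryocyte list mean was also lower in replicate 2, at 7.84 against 8.52, 8.07 against 9.30, 7.42 against 8.07 and 7.99 against 8.68 in the same order.

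Sox7 checked the induction in every sample. Its log2 level was 7.17 and 6.82 without doxycycline at 12 h, 10.96 and 10.82 with it, 6.96 and 6.84 without it at 24 h, and 10.65 and 10.57 with it. The rise was 3.89 ± 0.16 at 12 h (14.9-fold, adjusted p = 0.000387) and 3.71 ± 0.16 at 24 h (13.1-fold, adjusted p = 0.000554). The values cannot separate the transgene from the endogenous gene. The other SoxF genes did not pass: Sox17 differed by 0.26 ± 0.18 and 0.74 ± 0.18 and Sox18 by 0.10 ± 0.33 and 0.18 ± 0.33 at 12 h and 24 h (adjusted p = 0.847, 0.125, 0.995 and 0.957). The 3 genes were too few for a list test.

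At 12 h with doxycycline, 6 of 19 arterial and Notch genes rose and 8 of 22 erythroid genes fell. The largest rise was in Aldh1a3, a retinaldehyde dehydrogenase that makes retinoic acid, at 4.02 ± 0.19 (16.3-fold, adjusted p = 0.000483). Gja4, a gap junction protein of arterial endothelium, rose by 3.32 ± 0.52 (10.0-fold, adjusted p = 0.0387), and Hey1, a Notch target and transcriptional repressor, rose by 2.81 ± 0.23 (adjusted p = 0.00664). The parathyroid hormone receptor Pth1r rose by 3.16 ± 0.22, the water channel Aqp1 by 2.96 ± 0.21 and the platelet-derived growth factor gene Pdgfb by 2.51 ± 0.33 (adjusted p = 0.00364, 0.00364 and 0.0253). Dpysl3, Pga5 and Upp1 rose by 2.70 ± 0.30, 2.62 ± 0.41 and 2.60 ± 0.27 (adjusted p = 0.0143, 0.0387 and 0.0118).

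The largest fall at 12 h was in Emilin2, an extracellular matrix glycoprotein, at -1.92 ± 0.17 (3.80-fold, adjusted p = 0.00831). Trim10, needed for terminal erythroid differentiation, fell by 1.59 ± 0.16, the mitochondrial iron importer Slc25a37 by 1.57 ± 0.24 and the red cell anion exchanger Slc4a1 by 1.56 ± 0.22 (adjusted p = 0.0103, 0.0363 and 0.0292). Mybpc3, Tuba8 and Trpv2 fell by 1.86 ± 0.31, 1.79 ± 0.22 and 1.71 ± 0.27, and Slc16a10, P2ry14 and Acp5 by 1.62 ± 0.23, 1.58 ± 0.18 and 1.55 ± 0.19 (adjusted p from 0.0165 to 0.0461). In all, 151 probe sets passed, 97 higher and 54 lower, of which 92 and 40 changed at least 2-fold. With the replicate number as a block 467 passed.

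**Figure D1:**
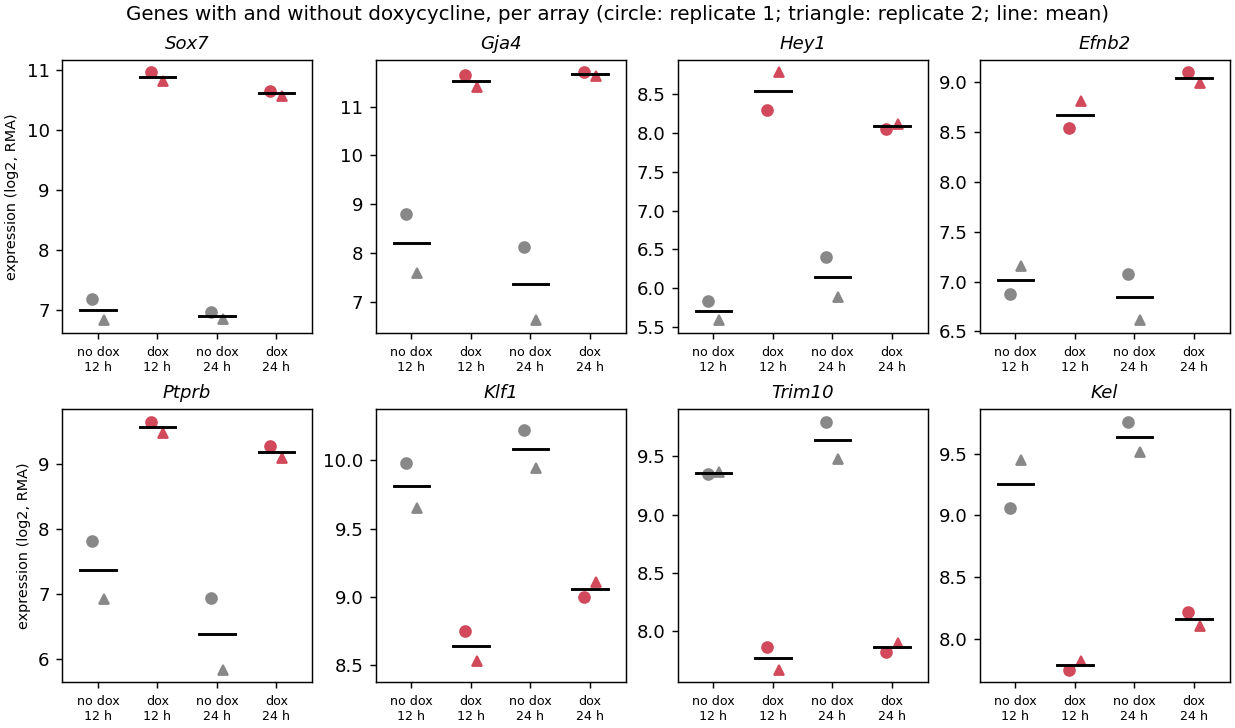
Log2 expression (RMA, y axis) of 8 genes on each array by group (x axis), with a circle for replicate 1, a triangle for replicate 2 and a line at the group mean of 2 arrays. Sox7 stood at 10.57 to 10.96 on the 4 arrays with doxycycline and at 6.82 to 7.17 on the 4 arrays without it, and each y axis has its own range.

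Of 19 measured arterial and Notch genes, 6 rose and 0 fell at 12 h, and 7 rose when adjusted over the list alone. Beside Hey1 and Gja4 these included the arterial ligand Efnb2 at 1.65 ± 0.20, the Notch ligand Jag2 at 1.98 ± 0.28 and Notch1 at 1.18 ± 0.18 (adjusted p = 0.0208, 0.0312 and 0.0346). The list median was 0.53 and the list lay above the other probe sets (camera adjusted p = 2.78e-12; adjusted p = 0.249 with an estimated correlation). Among 37 endothelial surface and junction genes 0 passed over all probe sets and 11 rose when adjusted over the list alone. With the replicate number as a block 11 rose and 0 fell. Their median was 0.72 (camera adjusted p = 1.16e-11; adjusted p = 0.613 with an estimated correlation), and the endothelial phosphatase Ptprb differed by 2.20 ± 0.39 (adjusted p = 0.0594). Of 13 basement membrane genes the collagens Col4a1 and Col4a2 rose, by 1.11 ± 0.17 and 1.04 ± 0.17 (adjusted p = 0.0363 and 0.046). In that list 6 rose when adjusted over the list alone (median 0.25, camera adjusted p = 1.73e-05; adjusted p = 0.306 with an estimated correlation). The 9 venous and lymphatic genes had 0 that passed and 1 that rose when adjusted over the list alone (camera adjusted p = 0.668).

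Of 22 erythroid genes 8 fell and 0 rose at 12 h, and 14 fell when adjusted over the list alone. They included Trim10, the heme synthesis enzyme Cpox at -1.31 ± 0.15, the blood group protein Kel at -1.47 ± 0.17 and Rhag at -1.14 ± 0.14 (adjusted p = 0.0143, 0.0187 and 0.0219 for the last 3). The list median was -0.98 (camera adjusted p = 2.73e-21; adjusted p = 0.306 with an estimated correlation). The embryonic globins Hba-x and Hbb-y, looked up after the lists had been read, differed by -0.29 ± 0.14 and 0.09 ± 0.17 at levels of 13.20 to 13.65 (adjusted p = 0.673 and 0.983). These are values at 12 h, where 1 of the 22 erythroid genes had a fitted change above 0, against 0 at 24 h. Among 24 blood transcription factors Hhex rose by 1.73 ± 0.22 and the erythroid factor Klf1 fell by 1.17 ± 0.18 (adjusted p = 0.0228 and 0.0361). When adjusted over the list alone 3 rose and 10 fell. Their median was -0.27 (camera adjusted p = 0.00712; adjusted p = 0.703 with an estimated correlation). Of 18 megakaryocyte and platelet genes Plek fell by 1.43 ± 0.23 (adjusted p = 0.0447). In that list 2 fell when adjusted over the list alone (median -0.53, camera adjusted p = 0.00568; adjusted p = 0.741 with an estimated correlation).

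Among ETS factors, named beside SOX7 in the title of the series, few genes passed at 12 h. Ets1, which binds endothelial enhancers, rose by 1.74 ± 0.23 (adjusted p = 0.0241), and 1 of 18 passed, or 3 that rose when adjusted over the list alone. Elk3, Fli1 and the myeloid factor Spi1 differed by 1.11 ± 0.20, 1.68 ± 0.46 and -0.96 ± 0.32 (adjusted p = 0.0582, 0.221 and 0.351). The list median was 0.14 (camera adjusted p = 0.029; adjusted p = 0.741 with an estimated correlation).

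Genes of S phase, of G2 and M phase and of ribosome biogenesis had medians of -0.26, -0.24 and -0.23 at 12 h with 0 of 18, 0 of 20 and 0 of 16 members that passed, also when adjusted over the list alone. Their camera adjusted p-values were 6.14e-06, 0.000753 and 0.000293 (adjusted p = 0.703, 0.741 and 0.703 with an estimated correlation). Of 9 lymphoid markers Ebf1 rose by 2.33 ± 0.27 (adjusted p = 0.0163; list camera adjusted p = 0.000753; adjusted p = 0.306 with an estimated correlation). It was the only one that rose when adjusted over the list alone. The p53 targets had 0 of 16 that passed and 1 that fell when adjusted over the list alone (median -0.18, camera adjusted p = 0.0456; adjusted p = 0.741 with an estimated correlation). In lists that were not called, Slc18a2 rose by 1.72 ± 0.19, Ltbp1 by 2.36 ± 0.29, Ndrg1 by 1.54 ± 0.21, Dusp6 by 1.59 ± 0.22 and Lin28a by 1.74 ± 0.19 (adjusted p = 0.0143, 0.021, 0.0277, 0.0277 and 0.0124). These lists were mast cell genes, TGF-beta and BMP response genes, hypoxia genes, immediate early genes and pluripotency markers (camera adjusted p = 0.559, 0.299, 0.0702, 0.257 and 0.888). The myeloid, Wnt target, integrated stress response, mesenchyme, cardiac and endoderm lists had 0 members that passed (camera adjusted p = 0.0894, 0.504, 0.156, 0.504, 0.535 and 0.662).

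The number of probe sets called at 12 h moved when 1 array was left out. Such a fit keeps only 1 sample in a group, which is then assumed to vary like the others, and it loses residual degrees of freedom. The number therefore does not by itself show dependence on a particular array. It was 11 and 7 without replicate 1 or 2 of the group without doxycycline at 12 h, 39 and 7 without replicate 1 or 2 of the group with it, and 47 without either array with doxycycline at 24 h. Without replicate 1 of the group lacking doxycycline at 12 h or replicate 2 of the group with it, the megakaryocyte shift was -0.11 and -0.12 (adjusted p = 0.26 and 0.197) and the G2 and M phase shift -0.07 and -0.10 (adjusted p = 0.484 and 0.227). The ETS shift was 0.29 without the first array with doxycycline and 0.21 without the second array lacking it (adjusted p = 0.0698 and 0.116), each without a call. The p53 shift was -0.07 without the first array lacking doxycycline at 12 h, -0.15 and -0.09 without the first or second given it at 12 h, and -0.12 without either given it at 24 h (adjusted p = 0.259, 0.0527, 0.155 and 0.0556). It was -0.09 after a repeated quantile normalization, -0.10 without the dimmest probe sets and -0.12 with the replicate block (adjusted p = 0.0507, 0.148 and 0.0674).

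At 24 h with doxycycline, 8 of 19 arterial and Notch genes and 3 of 37 endothelial genes rose, and 7 of 22 erythroid genes and 4 of 26 myeloid genes fell. Gja4 rose by 4.29 ± 0.52 (19.6-fold, adjusted p = 0.0152), Aqp1 by 3.80 ± 0.21 (adjusted p = 0.000989) and a second arterial gap junction gene, Gja5, by 3.01 ± 0.31 (adjusted p = 0.0102). The membrane-bound semaphorin Sema7a rose by 3.19 ± 0.20, Clic6 by 3.16 ± 0.16 and Gpm6a by 3.00 ± 0.53 (adjusted p = 0.00201, 0.000983 and 0.0442). The ectonucleotidase Entpd1 rose by 2.91 ± 0.33, Ptprb by 2.81 ± 0.39 and Pdgfb by 2.81 ± 0.33 (adjusted p = 0.0127, 0.0224 and 0.0138).

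The largest falls at 24 h included Gpr141 at -2.28 ± 0.38, the myeloid lectin Clec5a at -2.12 ± 0.35 and the leukocyte surface protein Cd52 at -2.04 ± 0.23 (adjusted p = 0.039, 0.036 and 0.0127). The red cell pyruvate kinase gene Pklr fell by 1.90 ± 0.22, the quinone reductase Nqo1 by 1.84 ± 0.14, and Trim10 and Ermap, a protein of the erythroblast membrane, by 1.78 ± 0.16 and 1.70 ± 0.28 (adjusted p = 0.0127, 0.0041, 0.0064 and 0.0359). P2ry14, Tuba8 and Trpv2 fell by 1.79 ± 0.18, 1.75 ± 0.22 and 1.71 ± 0.27 (adjusted p = 0.0101, 0.0169 and 0.0326). In all, 235 probe sets passed, 145 higher and 90 lower, of which 125 and 64 changed at least 2-fold. With the replicate number as a block 677 passed.

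Of 19 arterial and Notch genes 8 rose and 0 fell at 24 h, and 14 rose when adjusted over the list alone. Efnb2 rose by 2.20 ± 0.20, the Notch ligand Dll4 by 2.42 ± 0.25 and Hey1 by 1.94 ± 0.23 (adjusted p = 0.00708, 0.0101 and 0.0138). The list median was 1.17 (camera adjusted p = 1.33e-18; adjusted p = 0.116 with an estimated correlation). Of 37 endothelial surface and junction genes 3 rose: Ptprb, Tspan18 by 5.68-fold and the adhesion molecule Icam2 by 1.63 ± 0.30 (adjusted p = 0.0127 and 0.0496 for the last 2). When adjusted over the list alone, 19 rose and 0 fell, and the median was 1.05 (camera adjusted p = 2.88e-15; adjusted p = 0.367 with an estimated correlation). With the replicate number as a block 17 of the 37 endothelial genes rose and 0 fell. The endothelial cadherin Cdh5 differed by 2.01 ± 0.38 (adjusted p = 0.0571). Of 13 basement membrane genes 5 rose, Col4a2, Col4a1, Hspg2, Col18a1 and Sparc, by 1.42 ± 0.17, 1.39 ± 0.17, 1.23 ± 0.19, 1.18 ± 0.17 and 1.01 ± 0.16 (adjusted p from 0.0152 to 0.0334). When adjusted over the list alone 9 rose (median 0.91, camera adjusted p = 2.37e-12; adjusted p = 0.149 with an estimated correlation).

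Of 22 erythroid genes 7 fell and 0 rose at 24 h, and 17 fell when adjusted over the list alone. Kel fell by 1.48 ± 0.17, Rhag by 1.08 ± 0.14 and Cpox by 1.04 ± 0.15 (adjusted p = 0.0139, 0.0193 and 0.0224). The list median was -0.92 (camera adjusted p = 1.55e-21; adjusted p = 0.282 with an estimated correlation). Of 26 myeloid and macrophage genes 4 fell, the oxidase subunit Ncf1 by 1.56 ± 0.17, the actin regulator Coro1a by 1.59 ± 0.18, the lipopolysaccharide co-receptor Cd14 by 1.24 ± 0.16 and the macrophage growth factor receptor Csf1r by 0.85 ± 0.15 (adjusted p = 0.0116, 0.0127, 0.0165 and 0.0412). When adjusted over the list alone 9 fell and 1 rose (median -0.60, camera adjusted p = 9.76e-11; adjusted p = 0.282 with an estimated correlation). Among 24 blood transcription factors Mecom rose by 2.37 ± 0.27 and Klf1 fell by 1.03 ± 0.18 (adjusted p = 0.0127 and 0.0429). When adjusted over the list alone 2 rose and 5 fell (camera adjusted p = 0.599). Of 18 ETS factors Ets1 and Elk3 rose, by 1.57 ± 0.23 and 1.15 ± 0.20 (adjusted p = 0.024 and 0.0409). In that list 3 rose when adjusted over the list alone (median 0.11, camera adjusted p = 0.0132; adjusted p = 0.898 with an estimated correlation).

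**Figure D2:**
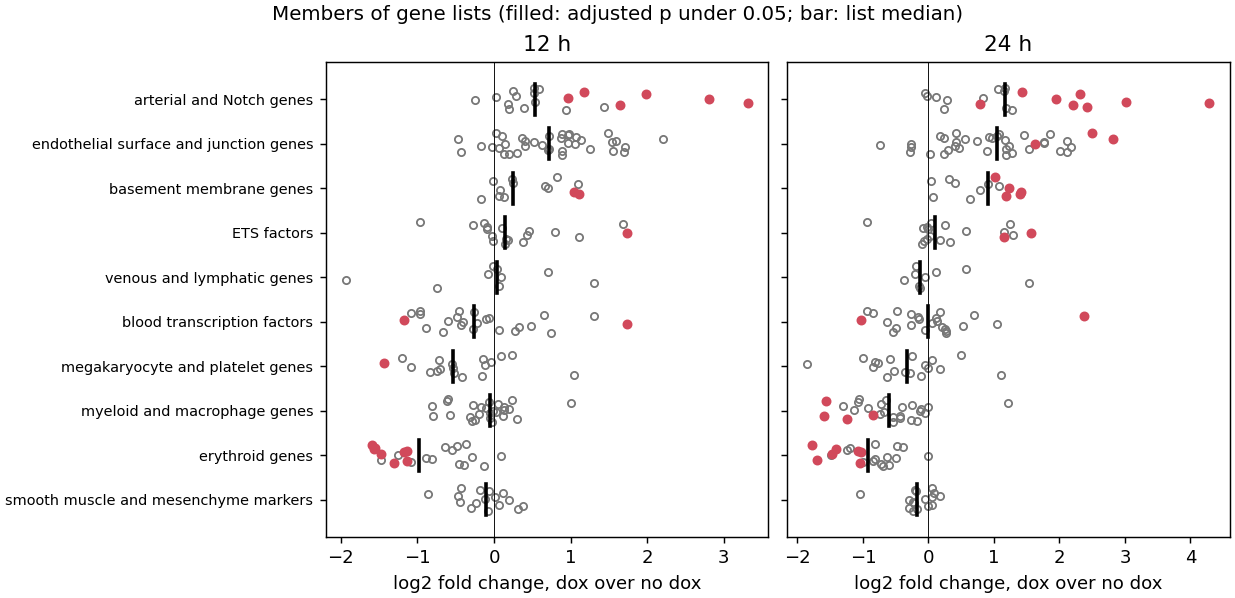
Log2 fold change with over without doxycycline (x axis) of each measured member of 10 gene lists (y axis) at 12 h and 24 h, filled where the adjusted p was under 0.05, with a bar at the list median. The arterial and Notch median lay at 0.53 and 1.17, the endothelial median at 0.72 and 1.05 and the erythroid median at -0.98 and -0.92.

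Hypoxia and glycolysis genes had 0 of 15 that passed at 24 h and 6 that rose when adjusted over the list alone (median 0.42, camera adjusted p = 3.97e-06; adjusted p = 0.282 with an estimated correlation). In the TGF-beta and BMP response list Ltbp1, which binds latent TGF-beta, rose by 1.90 ± 0.29 (adjusted p = 0.03). In that list 2 rose when adjusted over the list alone (camera adjusted p = 0.0177; adjusted p = 0.897 with an estimated correlation). Of 16 p53 targets Plk2 rose by 1.34 ± 0.24 and Btg2 fell by 0.92 ± 0.17 (adjusted p = 0.0476 and 0.0487). In that list 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0111; adjusted p = 0.898 with an estimated correlation). The megakaryocyte, S phase, G2 and M phase and ribosome biogenesis lists had 0 members that passed, also when adjusted over the list alone, with medians of -0.32, -0.16, -0.14 and -0.12 and camera adjusted p = 0.035, 0.0214, 0.0361 and 0.026 (adjusted p = 0.934, 0.931, 0.934 and 0.931 with an estimated correlation). Slc18a2, Lin28a and Ebf1 rose by 1.40 ± 0.19, 2.06 ± 0.19 and 2.08 ± 0.27 (adjusted p = 0.0218, 0.00677 and 0.0179) in the mast cell, pluripotency and lymphoid lists, which were not called (camera adjusted p = 0.856, 0.98 and 0.518). The venous, Wnt target, stress response, immediate early, mesenchyme, cardiac and endoderm lists had 0 members that passed (camera adjusted p = 0.68, 0.599, 0.597, 0.745, 0.597, 0.755 and 0.856). Median, mean and camera direction differed in sign in some lists without a call, among them the venous list at 24 h with a median of -0.13 and a mean of 0.13.

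The count at 24 h was 4 and 8 without replicate 1 or 2 of the group with doxycycline at 24 h, 150 without the second array lacking it, and 141 or 124 without either 12 h array lacking or given doxycycline. Without the first array lacking doxycycline at 24 h the megakaryocyte shift turned to 0.20 (adjusted p = 0.928), and the S phase, G2 and M phase, ribosome, TGF-beta and p53 shifts were -0.06, -0.03, -0.13, 0.26 and -0.05 (adjusted p from 0.132 to 0.753). Without the second array given doxycycline the megakaryocyte shift was 0.00 and the other 5 were -0.09, -0.11, -0.15, 0.08 and -0.10 (adjusted p from 0.121 to 0.682). The ETS shift was 0.29 without the first array given doxycycline and 0.17 without the second lacking it (adjusted p = 0.0687 and 0.244). Other settings also ended calls at 24 h. The megakaryocyte shift was -0.37 after quantile normalization and -0.35 after centring (adjusted p = 0.0685 and 0.067). The TGF-beta shift was 0.24 after quantile normalization and 0.28 with the replicate block (adjusted p = 0.123 and 0.0763). The G2 and M phase shift was -0.17 with array weights (adjusted p = 0.0587), and the S phase and ribosome shifts were -0.13 and -0.15 with only the groups compared (adjusted p = 0.0704 for each).

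The genes of the sort gate, looked up for the sort and not by the naming rule, gave no call. Cd34 differed by -0.43 ± 0.43 at 12 h and -0.28 ± 0.43 at 24 h, and Itga2b, which encodes CD41, by -0.71 ± 0.37 and 0.18 ± 0.37 (adjusted p = 0.939, 0.938, 0.711 and 0.964).

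The doxycycline effects at the 2 times came from separate arrays, but from 1 fit that shares the variance of each probe set. The calls at the 2 times are therefore not independent, and the overlaps of independent sets below are a reference only. Of the 97 probe sets higher at 12 h and the 145 higher at 24 h, 61 were in both sets, where 0.86 would be shared by independent sets. Of the 54 and 90 lower, 34 were in both, where 0.30 would be shared. Across all probe sets, which are not independent replicates, the effects correlated with Pearson's r = 0.60 and Spearman's rho = 0.41. Among the 291 that passed at either time 284 had the same sign at both, and 0 of those that passed at both had opposite signs.

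**Figure D3:**
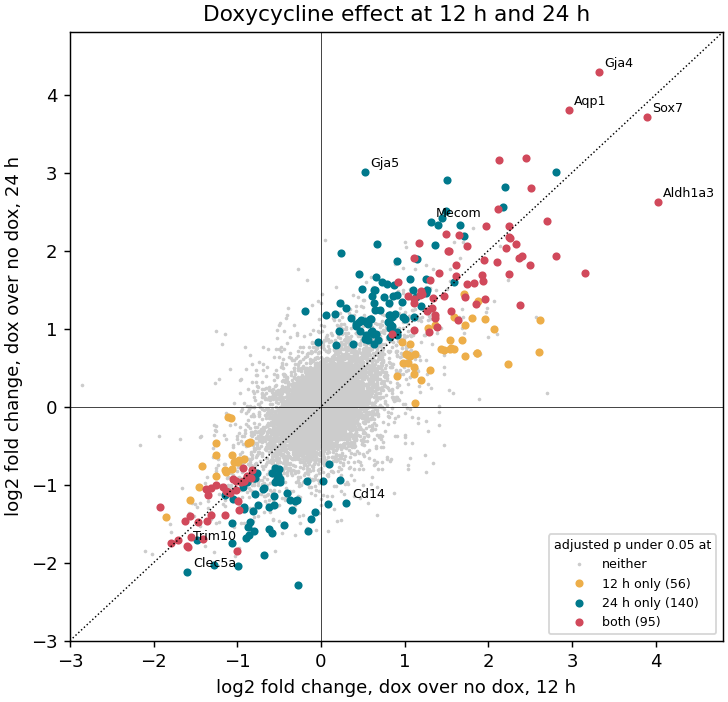
Log2 fold change with over without doxycycline at 12 h (x axis) and 24 h (y axis) for each probe set, coloured by the time at which its adjusted p was under 0.05, with a dotted line of equal change. Sox7 lies at 3.89 and 3.71 and Gja5 at 0.53 and 3.01.

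The difference between the effects was tested by itself, and 0 probe sets passed in limma, with 505 at an unadjusted p under 0.05 where 817 would be expected by chance. The count was 0 under every alternative fit and without each array. The simulations placed the same changes at both times, so no difference was simulated and the size detectable with these arrays is not known. Gja5 showed a difference of 2.48 ± 0.44 (unadjusted p = 0.000626, adjusted p = 1) and Cd14 one of -1.54 ± 0.22 (unadjusted p = 0.000156, adjusted p = 1), both chosen after their values were seen.

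Over both times, with 4 arrays against 4 and time in the model, 723 probe sets passed, 427 higher and 296 lower with doxycycline, and 1231 passed with the replicate number as a block. Of 37 endothelial genes 13 rose and 0 fell, or 20 with the block and 22 when adjusted over the list alone (median 0.90, camera adjusted p = 6.88e-16; adjusted p = 0.343 with an estimated correlation). They included Cdh5 at 1.78 ± 0.27 (adjusted p = 0.00854), named here after its value was seen. Of 22 erythroid genes 13 fell and 0 rose, or 20 with the block and 21 when adjusted over the list alone (median -0.94, camera adjusted p = 1.19e-23; adjusted p = 0.23 with an estimated correlation). Of 19 arterial and Notch genes 8 rose, and 14 when adjusted over the list alone (camera adjusted p = 6.88e-16; adjusted p = 0.126 with an estimated correlation). Of 18 ETS factors Fli1, Ets1, Ets2 and Elk3 rose and Spi1 fell (camera adjusted p = 0.00634; adjusted p = 0.553 with an estimated correlation). Spi1 stood at -0.95 ± 0.21 (adjusted p = 0.0436), and 4 rose and 1 fell when adjusted over the list alone. Of 13 basement membrane genes 6 rose, and 8 when adjusted over the list alone (camera adjusted p = 1.69e-09; adjusted p = 0.271 with an estimated correlation). Of 26 myeloid genes 4 fell and 1 rose, the same when adjusted over the list alone (median -0.31, camera adjusted p = 9.35e-06; adjusted p = 0.476 with an estimated correlation). Of 15 hypoxia genes 2 rose, or 5 with the block and 4 when adjusted over the list alone (camera adjusted p = 0.000297; adjusted p = 0.343 with an estimated correlation). Of 18 megakaryocyte genes 2 fell and 0 rose, or 4 fell and 1 rose with the block, and 3 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0045; adjusted p = 0.565 with an estimated correlation).

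The count over both times was 377, 412, 442, 447 and 454 without replicate 1 or 2 with doxycycline at 24 h, replicate 2 without or with it at 12 h, or replicate 1 with it at 12 h.

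From 12 h to 24 h without doxycycline, 4 of 15 hypoxia genes and 3 of 26 myeloid genes rose, as did a pair of metallothioneins. The metal-binding proteins Mt2 and Mt1 rose by 4.09 ± 0.28 (17.1-fold) and 2.38 ± 0.23, Clec5a by 3.41 ± 0.35, the mitophagy receptor Bnip3 by 2.94 ± 0.28 and Plekha2 5.66-fold (adjusted p from 0.0173 to 0.0223). The vasoconstrictor gene Edn1 fell by 1.54 ± 0.18 (adjusted p = 0.0295). It was the only fall among 24 probe sets that passed, of which 23 were higher. Of 15 hypoxia and glycolysis genes 4 rose, Bnip3, Ndrg1 at 1.82 ± 0.21, Egln3 at 1.37 ± 0.16 and Ero1a at 1.18 ± 0.13 (adjusted p = 0.0295, 0.0298 and 0.0263 for the last 3). In that list 14 rose when adjusted over the list alone (median 1.08, camera adjusted p = 1.9e-21; adjusted p = 0.149 with an estimated correlation). Of 26 myeloid genes Coro1a, Ncf1 and Cd14 rose, by 1.84 ± 0.18, 1.72 ± 0.17 and 1.66 ± 0.16 (adjusted p = 0.0223 for each). In that list 17 rose when adjusted over the list alone (median 0.79, camera adjusted p = 1.5e-20; adjusted p = 0.195 with an estimated correlation). This comparison and the doxycycline effect at 24 h share the arrays without doxycycline at 24 h, so a chance rise on those arrays would appear as a fall in the other comparison. List members named for the time comparisons are those that passed.

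Smaller list shifts were also called over time without doxycycline. The erythroid, megakaryocyte and G2 and M phase lists had medians of 0.29, 0.32 and 0.27, with 0 members that passed and 3, 0 and 0 that rose when adjusted over the list alone. Their camera adjusted p-values were 3.94e-07, 0.00542 and 1.3e-05 (adjusted p = 0.661, 0.872 and 0.774 with an estimated correlation). The ribosome, basement membrane and TGF-beta lists had medians of -0.28, -0.26 and -0.21, with 0 members that passed and 0, 1 and 1 that fell when adjusted over the list alone. Their camera adjusted p-values were 1.35e-06, 0.00118 and 0.0189 (adjusted p = 0.661, 0.586 and 0.774 with an estimated correlation). Among 18 stress response genes Vldlr rose by 1.76 ± 0.15 (adjusted p = 0.0223), also when adjusted over the list alone (list camera adjusted p = 0.00171; adjusted p = 0.586 with an estimated correlation).

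With doxycycline, 4 of 15 hypoxia genes rose from 12 h to 24 h. The vasodilator peptide gene Adm rose by 4.58 ± 0.50 (23.8-fold), Clec5a by 2.88 ± 0.35, the glycolytic enzyme Aldoc by 2.80 ± 0.26, the repressor Bhlhe40 by 2.64 ± 0.24 and Bnip3 by 2.63 ± 0.28 (adjusted p from 0.0167 to 0.0356). Edn1 fell by 2.61 ± 0.18, Sgk1 by 1.71 ± 0.18, Rhob by 1.29 ± 0.15 and Glul by 1.18 ± 0.15 (adjusted p = 0.00482, 0.023, 0.0309 and 0.04), the only falls among 30 probe sets that passed. Of 15 hypoxia and glycolysis genes Bnip3, Adm, Egln3 and Ero1a rose, the last 2 by 2.11 ± 0.16 and 1.50 ± 0.13 (adjusted p = 0.00736 and 0.0116). Again 14 rose when adjusted over the list alone (median 1.20, camera adjusted p = 2.87e-31; adjusted p = 0.0742 with an estimated correlation). Of 19 arterial genes Gja5 rose by 2.54 ± 0.31 (adjusted p = 0.0368). Among them 4 rose when adjusted over the list alone (median 0.28, camera adjusted p = 7.12e-05; adjusted p = 0.442 with an estimated correlation). Among 26 myeloid genes 0 passed and 3 rose when adjusted over the list alone (median 0.30, camera adjusted p = 1.39e-07; adjusted p = 0.47 with an estimated correlation).

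Smaller shifts were called with doxycycline as well. The erythroid, megakaryocyte, S phase and G2 and M phase lists had medians of 0.35, 0.67, 0.14 and 0.40, with 0 members that passed and 3, 0, 0 and 0 that rose when adjusted over the list alone. Their camera adjusted p-values were 2.3e-05, 0.000138, 0.0057 and 8.05e-09 (adjusted p = 0.66, 0.678, 0.779 and 0.631 with an estimated correlation). The ribosome and Wnt target lists had medians of -0.21 and -0.18, with 0 members that passed and 0 and 1 that fell when adjusted over the list alone (camera adjusted p = 0.00015 and 0.00339; adjusted p = 0.66 and 0.559 with an estimated correlation). Vldlr rose by 2.47 ± 0.15 in the stress response list and Ier3 by 1.82 ± 0.18 in the immediate early list (adjusted p = 0.00482 and 0.019). Each list had 1 that rose when adjusted over the list alone, with medians of 0.16 and -0.33 (camera adjusted p = 0.000261 and 3e-04; adjusted p = 0.442 and 0.559 with an estimated correlation).

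**Figure D4:**
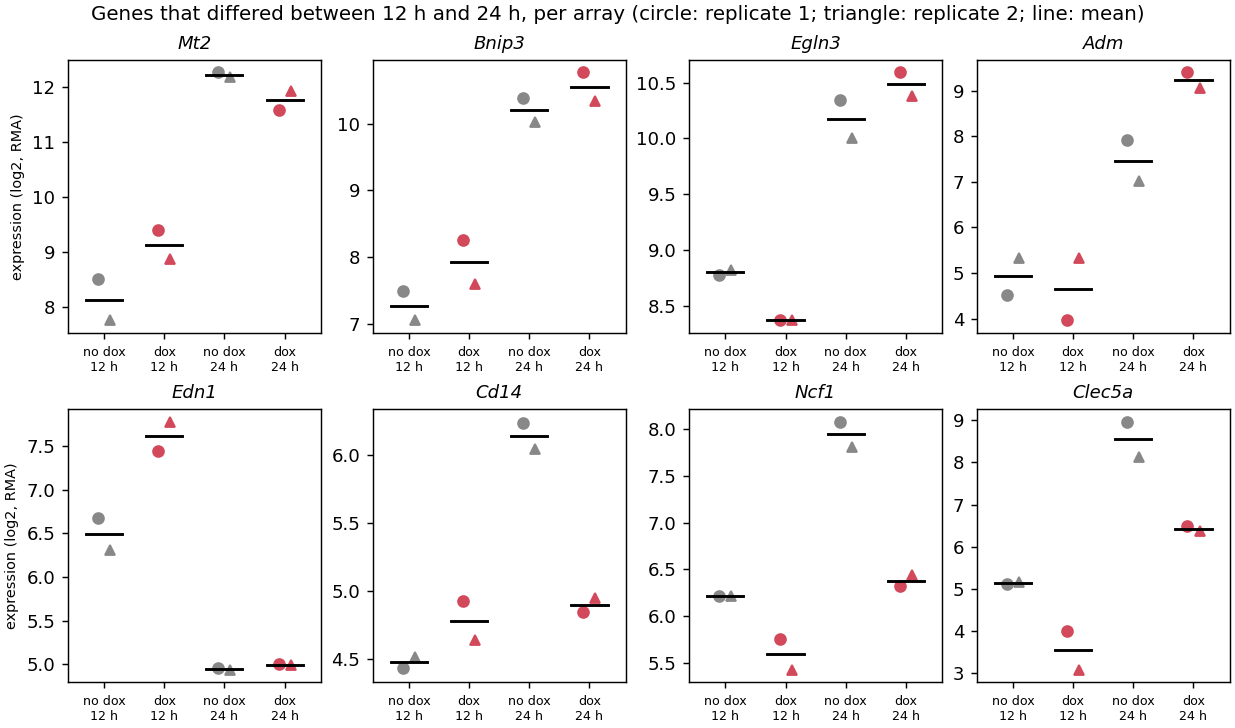
Log2 expression (RMA, y axis) of 8 genes on each array by group (x axis), with a circle for replicate 1, a triangle for replicate 2 and a line at the group mean of 2 arrays. Bnip3 had means of 7.27 and 7.92 at 12 h and of 10.20 and 10.55 at 24 h without and with doxycycline, and each y axis has its own range.

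Both time comparisons were small, and their counts moved when 1 array was left out. Such a fit keeps only 1 sample in a group and loses residual degrees of freedom. The counts also moved without arrays that are not part of the comparison. They therefore do not by themselves show dependence on a particular array. Without doxycycline the count of 24 was 1 and 3 without replicate 1 or 2 at 12 h and 0 without replicate 1 at 24 h, and it was 0 without either 24 h array with doxycycline. With doxycycline the count of 30 was 17 and 0 without replicate 1 or 2 at 12 h, 0 and 7 without replicate 1 or 2 at 24 h, and 14 without either 24 h array lacking doxycycline. The hypoxia list was called without each array in turn in both comparisons.

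Several of the smaller list shifts without doxycycline were lost without 1 array. Without the second 12 h array lacking doxycycline the G2 and M phase, megakaryocyte, TGF-beta and basement membrane shifts were 0.11, 0.16, -0.14 and -0.16 (adjusted p = 0.134, 0.332, 0.0738 and 0.0738). Without the first 24 h array lacking it they were 0.17, -0.06, -0.18 and -0.22 (adjusted p = 0.0797, 0.668, 0.195 and 0.0797). The TGF-beta shift was also lost without the second 24 h array lacking it, at -0.23, after quantile normalization, at -0.17, without the dimmest probe sets, at -0.18, and with the replicate block, at -0.20 (adjusted p = 0.0613, 0.121, 0.0585 and 0.0577). With doxycycline, the S phase and megakaryocyte shifts were 0.06 and 0.26 without the second 12 h array given it and 0.10 and 0.23 without the first 24 h array given it (adjusted p = 0.379, 0.0517, 0.0889 and 0.0974). The Wnt target and immediate early shifts were -0.30 and -0.07 without the second 12 h array given it, and the ribosome shift was -0.14 without the first (adjusted p = 0.0781, 0.182 and 0.062).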

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

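For the myeloid list, the fit without 1 array and the comparison with an estimated correlation were chosen as tests after the result was seen, and the test against random lists before it. The doxycycline effect on 5 gene lists differed between the times by a test of the difference itself (camera at the preset correlation), although 0 single genes did. None of the 5 was called with an estimated correlation or by fry.

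The myeloid and macrophage list, with a shift against other probe sets of -0.13 at 12 h and -0.61 at 24 h, differed by -0.48 (adjusted p = 3.4e-08). The second array without doxycycline at 24 h, whose values had an unusual distribution, did not produce it, since the difference was -0.63 without that array (adjusted p = 1.18e-08). Within same-numbered pairs the list mean changed with doxycycline by -0.06 at 12 h and -0.78 at 24 h in replicate 1. In replicate 2 the changes were -0.18 and -0.43, so the difference between the times rests more on replicate 1. A common shift of probe sets of similar level is argued against by a permutation test with 10000 random lists of the same levels, whose mean differences had a 95% range of -0.17 to 0.08 against -0.49 here (one-sided permutation p = 1e-04, the smallest these lists can give). The random lists were matched on the mean over all 8 arrays. Without doxycycline the myeloid list mean was 5.35 and 5.31 at 12 h against 6.41 and 5.98 at 24 h. Its genes may therefore have had less room to fall at 12 h, which was not tested. Replicate variation shared by myeloid genes stays open and cannot be told apart from an effect of culture time on the response to doxycycline, because the adjusted p of the difference was 0.542 with an estimated correlation. Fry, which tests the list against no change and not against other probe sets, gave an adjusted p of 0.639.

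The other 4 differences are values only. The arterial and Notch list differed by 0.43 (shift 0.92 at 12 h and 1.34 at 24 h, adjusted p = 0.000506; adjusted p = 0.542 with an estimated correlation). The basement membrane list differed by 0.34 (0.46 and 0.80, adjusted p = 0.000105; adjusted p = 0.542 with an estimated correlation). The endothelial list differed by 0.27 (0.73 and 1.00, adjusted p = 0.0231; adjusted p = 0.96 with an estimated correlation), and without a call by 0.01, 0.10, 0.12 and -0.06 (adjusted p from 0.385 to 0.877) without the first array lacking doxycycline at 12 h, the second given it at 12 h, the first given it at 24 h or the second lacking it at 24 h. The hypoxia list differed by 0.29 (0.19 and 0.48, adjusted p = 0.0434; adjusted p = 0.96 with an estimated correlation), and the call was lost with array centring, without the dimmest probe sets, with array weights and with the replicate block (adjusted p = 0.0599, 0.188, 0.0562 and 0.0758). It was also lost without any of 5 single arrays, where the difference was 0.36 and 0.22 without the 24 h arrays lacking doxycycline, 0.18 without the first given it at 24 h, and 0.23 and 0.26 without the second arrays lacking or given it at 12 h.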

How the results depend on the processing

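Counts of passing probe sets moved with several choices, in the order doxycycline at 12 h, doxycycline at 24 h, time without and time with doxycycline (151, 235, 24 and 30 as reported). A repeated quantile normalization gave 241, 415, 61 and 49. Leaving out the dimmest 33.3% gave 239, 367, 51 and 58. Array quality weights gave 495, 18, 0 and 88, with weights of 0.35 on both 24 h arrays lacking doxycycline and 1.26 to 1.53 on the others. An intensity trend gave 44 and 62 for the time comparisons. Fitting only the groups compared, which leaves 2 residual degrees of freedom, gave 0, 126, 1 and 0, and Sox7 at 12 h then stood at 3.89 with an adjusted p of 0.0695. With the replicate number as a block the counts were 467, 677, 130 and 123, and 1231 over both times against 723. Of 37 endothelial genes 11 then rose at 12 h and 17 at 24 h, and 0 fell. Of 22 erythroid genes 13 and 17 fell and 0 rose, and of 18 megakaryocyte genes 3 fell and 1 rose at each time. Of 99 calls of named genes, 44 were lost with array weights, 61 with only the groups compared, 7 after quantile normalization, and 29 to 79 without 1 array. None was lost with the block, centring, trend, robust eBayes or 1 probe set per gene. Of 145 results of named genes without a call, 37 gained one with the block, 17 with array weights and 11 after quantile normalization. Leaving out the dimmest probe sets added 12, the trend 10 and centring 8. Among called lists the block lost the p53 list at 12 h (adjusted p = 0.0674), the TGF-beta list at 24 h (0.0763) and over time without doxycycline (0.0577), and the hypoxia difference (0.0758). The cause of these changes was not tested.

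Camera with an estimated correlation called 0 lists at 12 h and 0 at 24 h, against 12 and 13, and fry called 1 and 3. Those called by fry were the arterial and Notch list at 12 h (fry adjusted p = 0.0232) and 3 lists at 24 h. The 3 were the arterial and Notch, basement membrane and erythroid lists (fry adjusted p = 0.0077, 0.0187 and 0.0399). Over both times fry called the same 3 lists (fry adjusted p = 0.00315, 0.0133 and 0.0043). From 12 h to 24 h it called the hypoxia list without and with doxycycline (fry adjusted p = 0.0104 and 0.00507). It also called the myeloid list over time without doxycycline (fry adjusted p = 0.0315). The endothelial shift against other probe sets was 0.73 at 12 h and 1.00 at 24 h, with camera adjusted p = 0.613 and 0.367 by the estimated correlation. Fry, which tests the list against no change and not this shift, gave adjusted p = 0.272 and 0.181. Robust eBayes was not run for lists. Nothing reversed its direction under the alternatives with all arrays.

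Leaving out each array in turn, the counts ranged from 7 to 201 for doxycycline at 12 h, 4 to 297 at 24 h, 0 to 0 for the difference, 0 to 36 and 0 to 29 for time without and with doxycycline, and 377 to 730 over both times. The lists called ranged from 10 to 13 at 12 h and 8 to 13 at 24 h. Sox7 ranged from 3.72 to 4.07 and 3.65 to 3.77, and the endothelial shift from 0.46 to 0.99 and 0.66 to 1.34. Without background values, the arrays limit what can be said of dim genes.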

Other observations

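The tests of dilution, of the erythroid share and of a stress response were chosen after the results were seen; those of chance, caveolae, retinoic acid and heme synthesis were written before theirs.

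Beside the lists of the report, 3 of 7 measured enzymes of heme synthesis changed at 24 h with doxycycline. Alad, Cpox and Uros fell, by 1.13 ± 0.20, 1.04 ± 0.15 and 0.96 ± 0.16 (adjusted p = 0.0483, 0.0224 and 0.0394), and the list mean was -0.92 (camera adjusted p = 8.17e-10; adjusted p = 0.077 with an estimated correlation). Fry gave the heme list an adjusted p of 0.0162. Cpox, Alas2, Urod and Fech also stand in the erythroid list. Cavin1, a coat protein of caveolae, rose by 2.53 ± 0.31 at 24 h (adjusted p = 0.0152), and was singled out after its value was seen. The other 7 caveola genes measured had 0 that passed and a mean of 0.47 (camera adjusted p = 0.0016; adjusted p = 0.077 with an estimated correlation), with Cav1 at 1.42 ± 0.41 (adjusted p = 0.197). Fry gave these 7 genes an adjusted p of 0.0286. A shared rise of caveola genes is a hypothesis only. Although Aldh1a3 makes retinoic acid, 6 genes of the retinoic acid response had 0 that passed and a mean of 0.16 at 24 h (camera adjusted p = 0.248), so a joint rise of these genes was not seen.

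Over both times 13 of 37 endothelial genes rose and 13 of 22 erythroid genes fell (list adjusted p = 0.343 and 0.23 with an estimated correlation, and fry adjusted p = 0.0725 and 0.0043). A fall of the erythroid share alone would raise the markers of other cell types alike, yet the myeloid minus endothelial list mean was lower with doxycycline in all 4 same-numbered pairs, by -1.23 on average (SD of the pairs 0.46), and by -1.86 (SD 0.60) without dim genes, which left 3 myeloid and 18 endothelial genes. The myeloid mean itself was lower in each pair, with changes of -0.06 and -0.18 at 12 h and -0.78 and -0.43 at 24 h. Their mean with the whole list was -0.36 (SD of the pairs 0.32), so the myeloid fall alone is not clear of the spread. The endothelial mean without dim genes rose by 1.20 (SD 0.44) and made up most of the -1.86. The 2 lists thus moved apart by more than the spread of the pairs. This cannot decide against a fall of the erythroid share alone, because the endothelial list was compared after its rise was seen. Most myeloid genes were also dim, and the part without dim genes holds only 3. Moreover, 4 pairs allow no exact two-sided sign-flip p below 0.125. Equal dilution of blood cells by a larger share of endothelial cells would lower erythroid and megakaryocyte genes alike, and with the whole lists the erythroid mean fell further in all 4 same-numbered pairs, by -0.53 on average (SD of the pairs 0.15, range -0.76 to -0.45). Some megakaryocyte genes are also made by endothelium (of those measured, Vwf, Selp, Thbs1 and Cd9) and dim genes can fall less, and without both kinds, with 19 erythroid and 6 megakaryocyte genes left, the difference was -0.31 (SD of the pairs 0.35, range -0.72 to 0.04). Dilution therefore cannot be told apart from a direct change of expression within the cells, which was not tested, and the CD41+ and CD34− sort preceded the culture, so endothelial cells could have arisen after it.

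For the 723 probe sets that passed over both times, 1 of the 35 splits of the 8 arrays, the real one, gave as many. That share lies under 0.05, the limit set beforehand, but it is the smallest possible and most splits ignore the pairing. The highest other split gave 76 and followed the replicate number. Among the 8 splits that part all 4 pairs the highest other gave 0. With 8 such splits no share under 0.05 can be reached, so the splits do not exclude chance. A stress response to doxycycline itself, for which no treated sample without the transgene was analysed here, stays open. The integrated stress response list was not called over both times (mean -0.13, camera adjusted p = 0.21), but 7 of its 18 genes were higher and the others not, so its mean decides nothing.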
